A study of Rattus norvegicus with 17 samples.

How the data were processed

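Gene expression was measured on Affymetrix rat arrays in laser captured, retrogradely labelled spinal cord neurons, 1000 per sample, from 10 µm cryosections of unfixed cord, after repeated rounds of RNA amplification. The deposited values were signal intensities per probe set on a linear scale, made by the authors with GCOS (Affymetrix GeneChip Operating Software; version and settings not stated). The mean without the lowest and highest 2% of signals was 200 to 200.1 on every array, so the arrays had been scaled as a whole, and they were used as deposited. The table held 31099 probe sets on 17 arrays, 1 array per sample, and 0 pairs of arrays were identical.

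An offset of 16, the 25th percentile of all signals, was added before taking log2. The 57 control probe sets and 12417 dim ones, below the 40th percentile of mean log2 signal, were left out, and 18625 were tested. Of these, 13224 had 1 gene symbol, 300 several and 5101 none, and the last 2 kinds were tested but not named. Of the probe sets in the whole table with 1 symbol, 20764 were matched to RefSeq genes by Entrez number, which changed 0 symbols. Sox11, Slc6a5 and Gadd45a, chosen in advance, were too dim and were not analysed here, and 1 other gene chosen in advance is not reported here.

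Groups were taken from the labels. Regenerating and non-regenerating samples were compared within the 7 animals that gave both, with the animal as a block, and each was compared with the 3 not axotomised samples between animals. The pairing came from the animal names in the labels. As a check, deviations from group means correlated between the samples of 1 animal with r = 0.34 to 0.71 over probe sets, and with r = 0.13 to 0.55 after the means of the name prefixes were removed. Tests used limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend) and a Benjamini-Hochberg adjusted p under 0.05 over the tested probe sets of each comparison. Log2 fold changes are given with the standard error of limma (SE) and group means of signal with SD.

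For 21 pathway and 11 cell type lists, 1 probe set per gene was used, the one with the highest mean. The lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and with fry, and adjusted over the 32 lists. Members were also counted with p adjusted over the list alone. The named genes were, per comparison, up to 12 that rose and 12 that fell with the smallest adjusted p under 0.05, at the probe set with the smallest p and with 1 symbol. Where fewer than 5 passed in a direction, those with the smallest p up to 5 were added as not passing. Up to 4 members of each list described with the smallest p, and a fixed set of injury, neuron and glia genes at their brightest probe set, completed the rule. Members of the motor neuron list beyond 4 and second probe sets were added after their values were seen. The groups, tests, lists, the naming rule and most alternatives were chosen before the data were examined.

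Array measures (3 prime to 5 prime ratios of Gapdh and beta-actin control probe sets, median signal, share of the 100 brightest probe sets and median correlation with the other arrays) were compared between groups with two-sided exact tests, by sign flips within animals and by permutation between animals. Principal components were described and not tested. The relation of the fold changes of pairs of comparisons, and the overlap of their calls, were set against 100 simulated data sets without change but with the same shared arrays. Their noise was drawn for each probe set on its own and holds no differences between whole arrays. The simulated overlaps, the simulated relations with arrays left out and the scores with astrocyte markers were added after the results were seen. Alternatives covered normalization, offset, filter, trend, array weights, the block, 3 prime bias, 1 fit over all samples, name prefixes, and leaving out each animal or array in turn. The calls were tested on simulated data with 200 changed probe sets of 18625. The noise there, too, was drawn for each probe set on its own, so the false calls do not cover those from differences between whole arrays. At a fold of 2, 78% were recovered in the comparison within animals and 10% and 12% in those between animals, with 3 to 5 false calls. At a fold of 4 the shares were 96%, 68% and 78%. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 drew the figures.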

Results

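The data were 17 arrays of gene expression in rat spinal cord neurons, each made from 1000 retrogradely labelled neurons collected by laser capture from 10 µm cryosections. Regenerating and non-regenerating neurons came from the same 7 rats, named MM11, MM13, MM14, MM16, MM17, MOON265 and MOON266, and gave 7 arrays per group. Traced neurons that had not been axotomised came from 3 other rats, named MM15, MM18 and MM19. Each array gave a signal for 31099 probe sets, of which 18625 were bright enough to be tested, with 1 or more tested probe sets for 10431 named genes. The number of arrays limits the precision of every value given here.

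The arrays were scaled to nearly the same mean, but their signals were spread differently. The median signal was 32.8 to 39.0 on the arrays of the MOON animals and 45.2 to 76.9 on those of the MM animals. The first principal component, with 37.5% of the variance, set the MOON animals (59.0 to 71.2) apart from the MM animals (at most 16.2). All not axotomised animals were MM animals, so the MOON animals entered the comparisons with that group on the axotomised side alone. The arrays of non-regenerating MM17 and not axotomised MM15 lay apart from the rest, with median correlations with the other arrays of 0.847 and 0.821. Their 100 brightest probe sets held 12.4% and 11.9% of the signal, against 3.85% to 7.31% elsewhere. Across 12 exact tests of 4 array measures between groups, the smallest p was 0.0167, for a median signal of 49.5 in regenerating and 68.9 in not axotomised samples, and its adjusted value was 0.20.

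**Figure D1:**
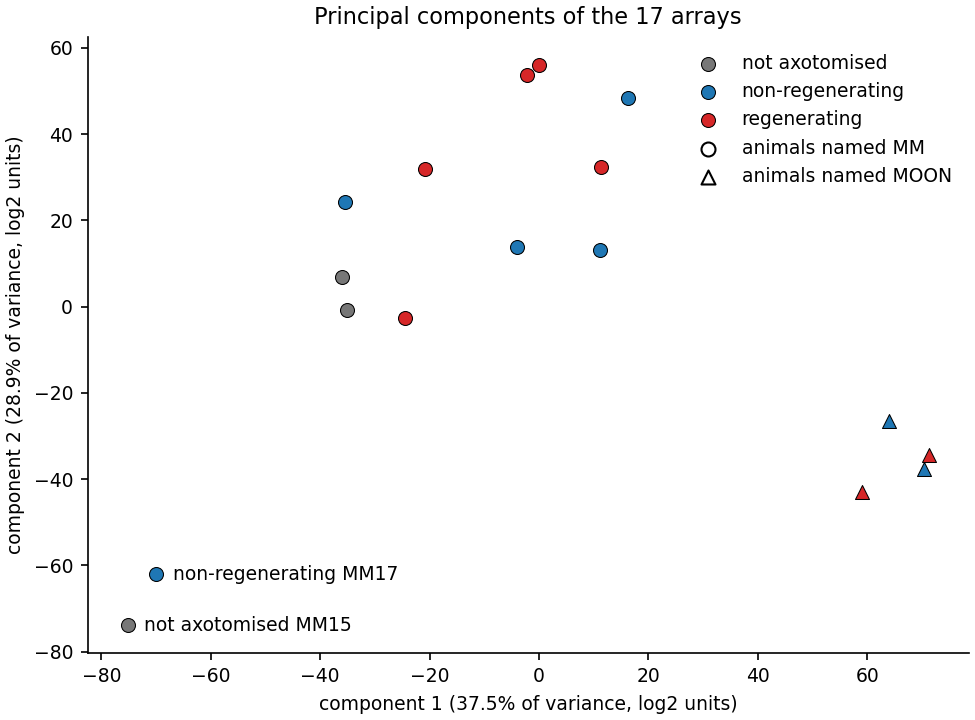
Principal components 1 and 2 of the 17 arrays (log2 units), with colours for the groups and shapes for the name prefix of the animal. The 4 MOON arrays lie at 59.0 or more on component 1, and non-regenerating MM17 and not axotomised MM15 lie at -69.9 and -75.2.

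The comparison of regenerating with non-regenerating neurons was made within animals and asks which genes go with regeneration. The neuropeptide genes Calca and Uts2 rose in the regenerating neurons. Calca, which encodes calcitonin and the sensory and motor neuropeptide CGRP, rose 4.64-fold (log2 fold change 2.22, SE 0.32, n = 7 pairs, adjusted p = 0.031 by limma), from a signal of 164 ± 88.1 (SD) to 946 ± 616. Uts2, which encodes the vasoactive peptide urotensin 2, rose 2.17-fold (log2 fold change 1.11, SE 0.17, n = 7 pairs, adjusted p = 0.042 by limma), from 54.9 ± 52.8 to 125 ± 72.5. Both were higher in the regenerating neurons of 7 of 7 animals. The two-sided exact sign-flip p was 0.0156 for each, unadjusted and the smallest that 7 pairs can give. Both genes were picked by their limma p in the same 7 animals, so this agreement and its p are not a separate test. Calca differed by 1.99 among the 5 MM animals and by 2.77 among the 2 MOON animals, and Uts2 by 1.11 and 1.12. A probe set with no gene name fell in 7 of 7 animals, with a log2 fold change of -1.37 (SE 0.18, adjusted p = 0.028 by limma). These 3 were the probe sets past the threshold, and 1318 had an unadjusted p under 0.05 in limma, where 931 would be reached by chance. No probe set passed limma in 10 of 21 other settings, among them quantile normalization, no replicate block, and the fits without MM11, MM13, MM14 or MM17, and 217 to 1923 had an unadjusted p under 0.05 there. Without MOON266, 1 passed, as did 1 among MM animals alone. Calca kept its call in 8 of 21 other settings, at 1.81 to 2.77, and Uts2 in 3 of 20, at 0.74 to 1.52.

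The motor neuron markers moved as a group. Of 14 measured members, 11 were higher in regenerating neurons, with a median log2 fold change of 0.84 and quartiles of 0.01 and 1.30. The list passed camera with an adjusted p of 2.1e-07 (adjusted p = 0.147 with an estimated correlation). In fry, which tests whether members move 1 way without comparing them with other genes, its adjusted p was 0.10. Adjusted over the list alone, 8 members rose. Besides Calca, they were Slc5a7, the choline transporter of cholinergic endings (1.24, SE 0.22), Calcb, which encodes beta-CGRP (2.07, SE 0.40, with a mean of 14.0 in non-regenerating samples, below the offset, which sets the size of the fold), Chodl, a lectin of fast motor neurons (1.32, SE 0.26), Prph, which encodes peripherin (0.90, SE 0.21), Chat, the enzyme of acetylcholine synthesis (1.15, SE 0.26), Slc10a4, a vesicle protein of cholinergic neurons (1.34, SE 0.31), and Slc18a3, the vesicular acetylcholine transporter (0.77, SE 0.24). Over all probe sets these 7 did not pass, with adjusted p of 0.24 to 0.68 by limma. The other 6 members were near 0 or lower, such as Ret, the receptor of GDNF signalling (0.03), Isl1, a transcription factor of motor and sensory neurons (-0.02), and Nefh, the heavy neurofilament (-0.32). The mean signal of Chat was 147 in regenerating, 51.0 in non-regenerating and 41.9 in not axotomised samples, and that of Slc5a7 was 700, 244 and 218. General neuron markers had a median of -0.12 (adjusted p = 0.096 by camera), and sensory ganglion markers, which share Calca, Prph and Isl1 with the motor neuron list, had a median of 0.03 (adjusted p = 0.16). Slc17a6, the vesicular glutamate transporter, and Gad1, the enzyme of GABA synthesis, differed by -0.14 (SE 0.16) and -0.38 (SE 0.19).

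**Figure D2:**
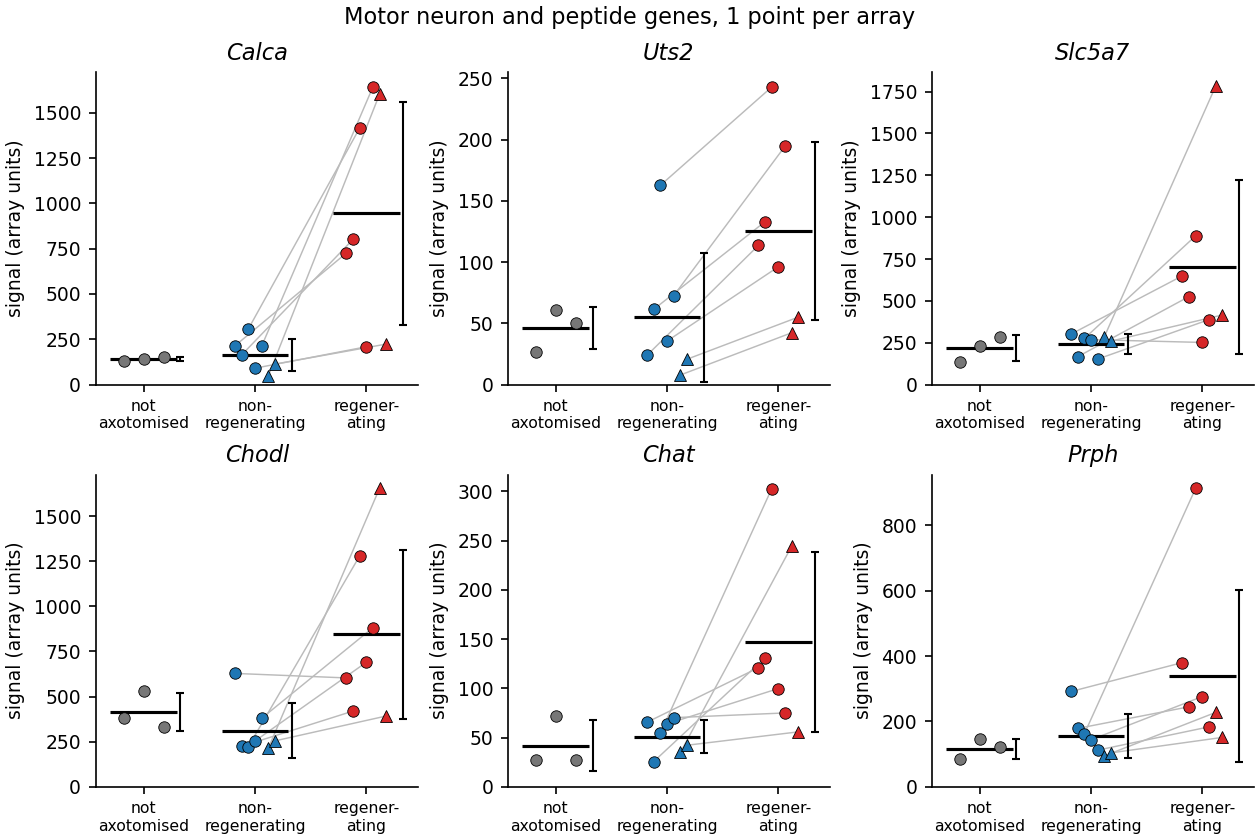
Signal of 6 genes on each of the 17 arrays (array units), with lines joining the samples of 1 animal, bars at group means, SD at their right, circles for MM and triangles for MOON animals. Calca, Uts2, Chat and Prph are higher in the regenerating sample of 7 of 7 animals, and Slc5a7 and Chodl of 6 of 7.

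Classical genes of the regenerating neuron did not pass between the regenerating and the non-regenerating samples of an animal. Gap43, a protein of growth cones, differed by -0.21 (SE 0.18), Atf3, a transcription factor induced by axotomy, by 0.20 (SE 0.21), and Gal, which encodes galanin, by 0.11 (SE 0.14). Sprr1a differed by 0.60 (SE 0.21), Hspb1, a small heat shock protein, by 0.58 (SE 0.25), Stat3, which carries cytokine signals, by 0.43 (SE 0.15), and Jun by 0.40 (SE 0.13). Several differed between the name prefixes, a difference that was not tested. In the MM and the MOON animals Gap43 differed by -0.42 and 0.30, Atf3 by -0.14 and 1.03, Gal by -0.05 and 0.52, Sprr1a by 0.24 and 1.52, and Stmn2 by -0.44 and 0.16. Over all animals, Stmn2, Tubb3 and Basp1, of the growing cytoskeleton, differed by -0.27, -0.07 and 0.03, and Nefl and Nefm by -0.04 and 0.04. Of 34 measured regeneration-associated genes, 25 were higher, with a median of 0.08, and 0 rose in limma, over all probe sets or adjusted over the list alone. At an unadjusted p under 0.05 in limma, 7 of the 34 were higher and 0 lower. Over all 18625 probe sets, 794 were higher and 524 lower at that p. The list did not pass camera (adjusted p = 0.067), but it passed in 5 of 23 other settings, which were array weights (median 0.11), without MM13 (0.07), without MM17 (0.15), without the 2 arrays that stood apart, which is the same fit in this comparison, and MOON animals alone (0.26). Among fixed genes of other kinds, Cd44 differed by -0.38, Fgf2 by 0.18, Ddit3 by 0.14, Gfap by -0.03, Mbp by -0.15 and Aif1 by 0.39, and none passed.

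Genes of protein turnover and synthesis were slightly higher in regenerating neurons. The ubiquitin-proteasome list had 35 of 42 members higher and a median of 0.17 (adjusted p = 8.0e-04 by camera, adjusted p = 0.658 with an estimated correlation), with Psmd1 at 0.48 and Psmb7 at 0.51. The ribosomal proteins had 34 of 43 members higher and a median of 0.13 (adjusted p = 0.0024 by camera, adjusted p = 0.658 with an estimated correlation), with Rpsa at 0.79 and Rplp0 at 0.43. The medians of both lists lay below 0 in the MOON animals, at -0.03 and -0.10, and the ribosomal list passed camera there with that lower median (adjusted p = 0.032). The ribosomal call ended without MM16 (median 0.11) or MM17 (0.08), the proteasome median was 0.10 without MM17, and both calls ended with 3 prime bias as a covariate (0.04 for ribosomal and 0.11 for proteasome genes). The other 29 lists did not pass camera, with medians of -0.12 to 0.14. Adjusted over their lists alone, Fgf1, a growth factor (0.58, SE 0.12), and Asns, an amino acid enzyme of the stress response (0.55, SE 0.13), rose, and Cat, which encodes catalase, fell (-0.73, SE 0.18). The named genes with the smallest p on the lower side did not pass over all probe sets. Besides Cat they were Zfpm1 (-0.84), Nol4 (-0.72), Pbk (-0.92) and Stambpl1 (-0.47), each with an adjusted p of 0.52.

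The comparison of non-regenerating with not axotomised neurons was made between animals and asks which genes go with axotomy. After axotomy 7 named genes rose. Cxcl13, a chemokine that attracts B cells, rose 40.6-fold (log2 fold change 5.34, SE 0.24, n = 7 and 3, adjusted p = 4.4e-08 by limma), from a signal of 49.2 ± 13.2 (SD) to 2656 ± 660. Plek, which encodes pleckstrin of blood and immune cells, rose 4.93-fold (2.30, SE 0.23, adjusted p = 7.5e-04), from 198 ± 45.3 to 1040 ± 209. Fcrl2, of the Fc receptor-like family, rose 4.29-fold (2.10, SE 0.25, adjusted p = 0.0038), and Fcgr2b, an inhibitory receptor for IgG, rose 5.08-fold (2.34, SE 0.34, adjusted p = 0.034). Lgals3, which encodes galectin-3 of activated macrophages, rose 3.22-fold (1.69, SE 0.25, adjusted p = 0.034), from 88.4 ± 31.8 to 315 ± 57.3. Pik3cd, a lipid kinase of leukocytes, rose by 1.69 (SE 0.27, adjusted p = 0.042), and Kazn, which encodes kazrin, by 1.68 (SE 0.26, adjusted p = 0.036). A probe set with no gene name rose by 1.90 (SE 0.29, adjusted p = 0.036). The second probe set of Pik3cd differed by -0.59, and the other 2 of Kazn by 0.07 and -0.64, none of them past the threshold. Kazn and the probe set with no gene name averaged 13.2 in not axotomised samples, below the offset of 16, so that their sizes depend on it, with 0.98 to 2.57 and 1.14 to 2.88 over the other settings. These 8 probe sets rose and 0 fell in limma, and 499 with an unadjusted p under 0.05 were higher and 1417 lower, against 1439 and 551 with each array centred on its median. With array weights, 553 probe sets passed as higher and 1887 as lower. Cxcl13 and Plek kept their calls in 23 of 23 other settings, Fcrl2 in 22, Fcgr2b and Lgals3 in 14 each, Kazn in 10 of 22 and Pik3cd in 8 of 22. The count was 2 without not axotomised MM18, 3 without not axotomised MM15 or non-regenerating MM11, MM13, MM14 or MOON266, 5 without MOON265 and 37 without non-regenerating MM17. Among MM animals alone 3 rose, and Cxcl13 differed by 5.45.

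Microglia and macrophage markers were higher as a group, with 21 of 26 members higher and a median of 0.81 (quartiles 0.14 and 1.36). The list passed camera with an adjusted p of 1.7e-12, and of 0.025 with an estimated correlation, and fry gave 0.0045 for it and 0.012 for astrocyte markers. Adjusted over the list alone, 14 members rose, such as Laptm5, a lysosomal protein of blood cells (1.39, SE 0.26), and C1qa, of the complement component C1q (1.38, SE 0.27), and over all probe sets Fcgr2b and Lgals3 rose. Aif1, the microglial protein Iba1, differed by 1.47 (SE 0.53, adjusted p = 0.47 over all probe sets). Astrocyte markers were higher too, with 19 of 22 members higher and a median of 0.30 (adjusted p = 4.0e-05 by camera, and 0.026 with an estimated correlation). Gfap, the astrocyte filament protein, differed by 1.37 (SE 0.24), from 1227 ± 236 to 3210 ± 679, and rose adjusted over the list alone (adjusted p = 0.072 over all probe sets). Vim, Slc1a3 and S100b of the same list differed by 0.70, 0.67 and 0.54. Oligodendrocyte, endothelial, fibroblast, Schwann cell, blood cell and general neuron markers had medians of 0.06, -0.11, -0.27, -0.22, -0.16 and -0.05, and none of these lists passed camera. The list of MHC, interferon and complement genes had a median of 0.26 and 6 members that rose adjusted over the list alone, such as Cd74, the invariant chain of MHC class II (1.08, SE 0.30), and Psmb8 and Psmb9, of the immunoproteasome (1.03, SE 0.28, and 1.33, SE 0.40, the latter from a mean of 7.60, below the offset). It passed camera (adjusted p = 0.0011, adjusted p = 0.507 with an estimated correlation), but not without not axotomised MM18 (0.19).

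**Figure D3:**
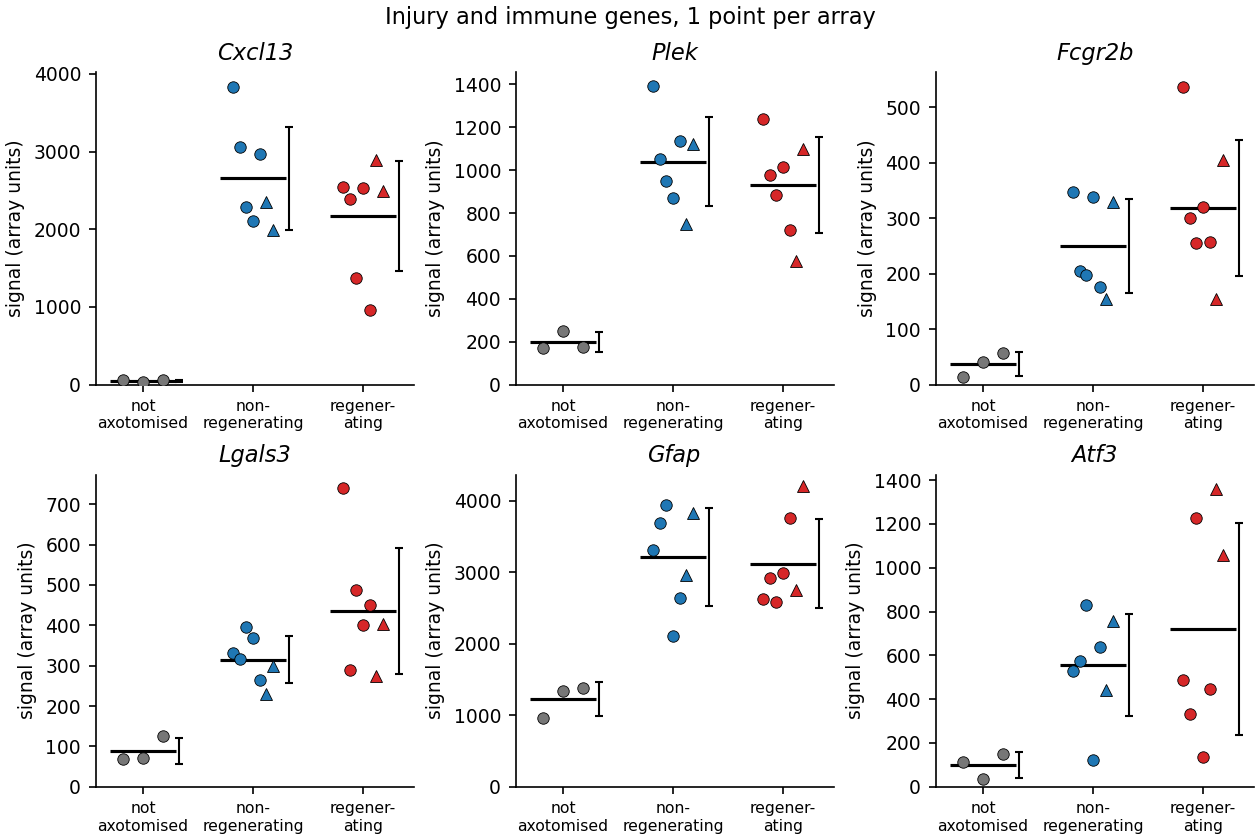
Signal of 6 genes on each of the 17 arrays (array units), with bars at group means, SD at their right, circles for MM and triangles for MOON animals. Cxcl13 averages 49.2 in not axotomised, 2656 in non-regenerating and 2167 in regenerating samples, and Gfap 1227, 3210 and 3116.

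Atf3 was higher after axotomy, by 2.32 (SE 0.50), from a signal of 99.1 ± 59.8 (SD) to 556 ± 232 (n = 3 and 7). It rose adjusted over the list of regeneration-associated genes alone (adjusted p = 0.20 over all probe sets, by limma). That list had a median of 0.27 (adjusted p = 0.0039 by camera, adjusted p = 0.508 with an estimated correlation) and did not pass without non-regenerating MM17 (0.20) or without not axotomised MM18 (0.19). Gal differed by 0.85 (SE 0.25), Vip, a neuropeptide, by 1.76 (SE 0.64), Cd44, an adhesion receptor, by 0.84 (SE 0.34), Gap43 by 0.38 (SE 0.47), Sprr1a by 0.27 (SE 0.42), Jun by 0.11 (SE 0.29), Hspb1 by 0.39 (SE 0.27) and Stat3 by -0.29 (SE 0.52). Growth cone genes had a median of 0.17 (adjusted p = 0.019 by camera, adjusted p = 0.571 with an estimated correlation). That call ended under quantile normalization (0.14), with the mean of all probe sets per gene (0.09), with the filter at the 70th percentile (0.15) and without non-regenerating MM17 (0.14) or not axotomised MM18 (0.10) or MM19 (0.08). Motor neuron markers had a median of 0.00 (adjusted p = 0.93), with Chat at 0.26 and Prph at 0.31. Adjusted over their lists alone, Tgfbr1, a receptor of TGF-beta (1.32, SE 0.23), Mt2A, a metal-binding stress protein (1.71, SE 0.29), and Fabp7, a lipid-binding protein of glia (1.23, SE 0.31), rose. Of the 32 lists, 21 did not pass camera, with medians of -0.27 to 0.08.

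Ribosomal and proteasome genes were higher in non-regenerating than in not axotomised neurons, and genes of excitability and lipid synthesis were lower. Ribosomal proteins had 39 of 43 members higher and a median of 0.36 (adjusted p = 5.4e-06 by camera, adjusted p = 0.513 with an estimated correlation), which was 0.08 without not axotomised MM15 and 0.22 with 3 prime bias as a covariate. The ubiquitin-proteasome list had a median of 0.22 (adjusted p = 0.0013, adjusted p = 0.729 with an estimated correlation), which was -0.08 and no longer past without MM15, 0.22 and no longer past with the filter at the 70th percentile, 0.04 with 3 prime bias as a covariate, 0.08 without the 2 arrays that stood apart, 0.13 without non-regenerating MM11, and 0.34 to 0.36 without non-regenerating MM17 or not axotomised MM18 or MM19. Transmitter receptors had a median of -0.27 (adjusted p = 0.048), voltage-gated channels of -0.21 (adjusted p = 0.040), neurotrophic factors and their receptors of -0.29 (adjusted p = 0.049) and cholesterol genes of -0.36 (adjusted p = 0.033). With an estimated correlation none of these 4 passed (adjusted p = 0.513, 0.508, 0.508 and 0.508). With each array centred on its median, which raised the median of all probe sets from -0.12 to 0.24, the 4 medians were 0.09, 0.15, 0.07 and 0.00. Centring moves all genes alike, and receptors and neurotrophic factors still passed camera there (adjusted p = 0.0040 and 0.039), while the other 2 did not (adjusted p = 0.053 and 0.079). Of 25 other settings, the calls ended in 11 for receptors, 11 for channels, 17 for neurotrophic factors and 7 for cholesterol genes. Each ended without non-regenerating MM16 or MM17 or not axotomised MM18 or MM19 (-0.12 to -0.40), all but that of cholesterol without MM15 (-0.18 to -0.29), and those of receptors and neurotrophic factors without MM11 or MM14 (-0.23 to -0.27). The receptor call also ended among MM animals alone and with the name prefix as a term (-0.17 in both) and with the filter at the 70th percentile (0.01), and it was kept at -0.17 and -0.15 without MOON265 and MOON266. The channel call also ended with array weights (-0.12), without the 2 arrays that stood apart (-0.14), with no filter (-0.22) and with the filter at the 70th percentile (-0.09), and it was kept at -0.12 among MM animals alone and -0.13 without MOON266. Chrna7, a nicotinic receptor subunit, fell adjusted over the receptor list alone (-1.68, SE 0.36, adjusted p = 0.20 over all probe sets). The named genes with the smallest p on the lower side, besides Chrna7, were Mlip (-1.60), Zdhhc19 (-1.54), Lurap1l (-1.02) and Icam2, an adhesion protein of endothelium and leukocytes (-1.30), and none passed.

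The comparison of regenerating with not axotomised neurons, between animals, completed the set of pairs and is not named in the study's design. Cxcl13 rose 32.0-fold (SE 0.32 on the log2 scale, n = 7 and 3, adjusted p = 5.1e-06 by limma), to 2167 ± 712 (SD), Fcgr2b rose 6.30-fold (log2 fold change 2.65, SE 0.36, adjusted p = 0.013), Fcrl2 rose 4.63-fold (2.21, SE 0.28), Plek rose 4.37-fold (2.13, SE 0.25) and Lgals3 rose 4.24-fold (2.08, SE 0.30). Blnk, an adaptor of B cell and macrophage signalling, rose by 1.54, Arhgap25, a Rac regulator of leukocytes, by 2.25, Laptm5 by 1.58, C1qa by 1.52, Rnaset2, a lysosomal ribonuclease, by 1.58, and Kazn by 1.94. The other 2 probe sets of Kazn differed by -0.07 and -1.14, and the second of Laptm5 by 0.51. Anxa3, which encodes annexin A3, rose by 2.07, and another of its 4 probe sets rose by 1.44. The remaining ones differed by 0.52 and 0.81 and did not pass. The not axotomised means of Anxa3 (10.3) and Kazn (13.2) lay below the offset, and their sizes ran from 1.23 to 3.23 and from 1.18 to 2.86 over the other settings. Mt2A rose by 1.68 (SE 0.27) and Gfap by 1.33 (SE 0.22, adjusted p = 0.026). On the other side, Lurap1l fell (-1.32, SE 0.22, adjusted p = 0.026), as did Uimc1, of DNA repair (-2.32, SE 0.39, adjusted p = 0.030), Notch3, a receptor of vascular mural cells (-1.67, SE 0.29, adjusted p = 0.032), Rab5b, of early endosomes (-1.33, SE 0.25, adjusted p = 0.049), and Tas2r121, a taste receptor gene (-1.73, SE 0.33, adjusted p = 0.049). The brightest of the 4 probe sets of Rab5b differed by -0.36 (SE 0.28), and the second of Uimc1 by -0.54 (SE 0.22). In all, 29 probe sets rose and 11 fell, 25 and 5 of them with a single gene name, for 24 and 5 genes. At an unadjusted p under 0.05 in limma, 1113 were higher and 3274 lower, against 3804 and 1322 with each array centred on its median.

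The number of calls in this comparison moved with the arrays and settings used. It was 1, 2 and 7 without not axotomised MM15, MM18 and MM19, 10 to 24 without regenerating MM11, MM13, MM14 or MOON266, and 1504 without regenerating MM17. With each array centred on its median, which raised the median of all probe sets from -0.13 to 0.27, 300 rose and 50 fell, and with an offset at the median of all signals 104 rose and 573 fell. Among MM animals alone 60 rose and 10 fell, and 31 of these 70 were among the 40. Cxcl13 passed in 23 of 23 other settings, Plek in 21, Fcrl2 in 20, and Fcgr2b and Lgals3 in 19 each. Of the genes that fell, Lurap1l passed in 15 of 23, Uimc1 in 12 of 22, Notch3 in 10 of 22, and Rab5b and Tas2r121 in 8 of 22 each. The 11 probe sets that fell became 1 with no offset or with the filter at the 70th percentile, and 0 with 3 prime bias as a covariate. Atf3 differed by 2.51 (SE 0.60, adjusted p = 0.068), Vip by 2.18 (SE 0.46), Calca by 2.24 (SE 0.58), Chat by 1.40 (SE 0.43) and Prph by 1.21 (SE 0.42), and none passed over all probe sets.

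Microglia and macrophage markers had 22 of 26 members higher and a median of 0.65 in regenerating against not axotomised neurons (adjusted p = 4.3e-09 by camera, adjusted p = 0.478 with an estimated correlation), with 5 members past the threshold over all probe sets and 11 adjusted over the list alone. Astrocyte markers had a median of 0.36 (adjusted p = 0.0054, adjusted p = 0.499 with an estimated correlation), and Gfap, Vim and Mlc1 rose adjusted over the list alone. Motor neuron markers had a median of 0.76 (adjusted p = 0.0057, adjusted p = 0.499 with an estimated correlation). Adjusted over that list alone 4 rose, among them Calca, Chat and Slc5a7, and Isl1 fell (-1.40, SE 0.38). The motor neuron median was 0.48 without not axotomised MM15 and 0.33 with 3 prime bias as a covariate, and with each array centred on its median the list did not pass (1.15). Regeneration-associated genes had a median of 0.30 (adjusted p = 0.0054, adjusted p = 0.499 with an estimated correlation), and adjusted over the list alone 5 rose, among them Vip, Atf3 and Klf7, a transcription factor of growing axons, and L1cam, an adhesion protein, fell. That call ended without not axotomised MM18 (0.22). Transmitter receptors had a median of -0.40 (adjusted p = 0.0057, adjusted p = 0.499 with an estimated correlation), and 7 members fell adjusted over the list alone, such as Chrna7 (-1.56), Chrm3, a muscarinic receptor (-1.40), Gabrg3, a GABA receptor subunit (-1.23), and Grm8, a metabotropic glutamate receptor (-1.24). With each array centred on its median the receptor median was -0.005, and the list still passed camera. Voltage-gated channels had a median of -0.28 (adjusted p = 0.044, adjusted p = 0.528 with an estimated correlation), which was 0.11 with each array centred on its median, and 9 members fell adjusted over the list alone, such as Kcnh2 (-1.06), Hcn2 (-1.10) and Kcnq3 (-0.95). The channel call ended in 12 of 25 other settings, among them the filter at the 70th percentile (-0.06), array weights (-0.16), MM animals alone and the name prefix as a term (-0.22 in both), no filter (-0.30), and the fits without regenerating MM11, MM17 or MOON266 or not axotomised MM18 or MM19 (-0.25 to -0.31).

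Genes of protein synthesis and turnover were higher too in regenerating than in not axotomised neurons. Ribosomal proteins had 40 of 43 members higher and a median of 0.53 (adjusted p = 7.6e-07 by camera, adjusted p = 0.548 with an estimated correlation), and Rps9 (0.92), Rpl5 and Rpl22 (0.76) rose adjusted over the list alone. The ubiquitin-proteasome list had 36 of 42 members higher and a median of 0.43 (adjusted p = 2.2e-05, adjusted p = 0.528 with an estimated correlation), and its call ended with 3 prime bias as a covariate (0.04). The ribosomal median was 0.15 with that covariate. Without not axotomised MM15 these medians were 0.25 and 0.18, and that of astrocyte markers was 0.24. The list of MHC, interferon and complement genes had a median of 0.35 (adjusted p = 0.0054, adjusted p = 0.528 with an estimated correlation), with 9 members that rose and 5 that fell adjusted over the list alone, and its call ended without not axotomised MM18 (0.26). The other 23 lists did not pass camera, with medians of -0.47 to 0.20.

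**Figure D4:**
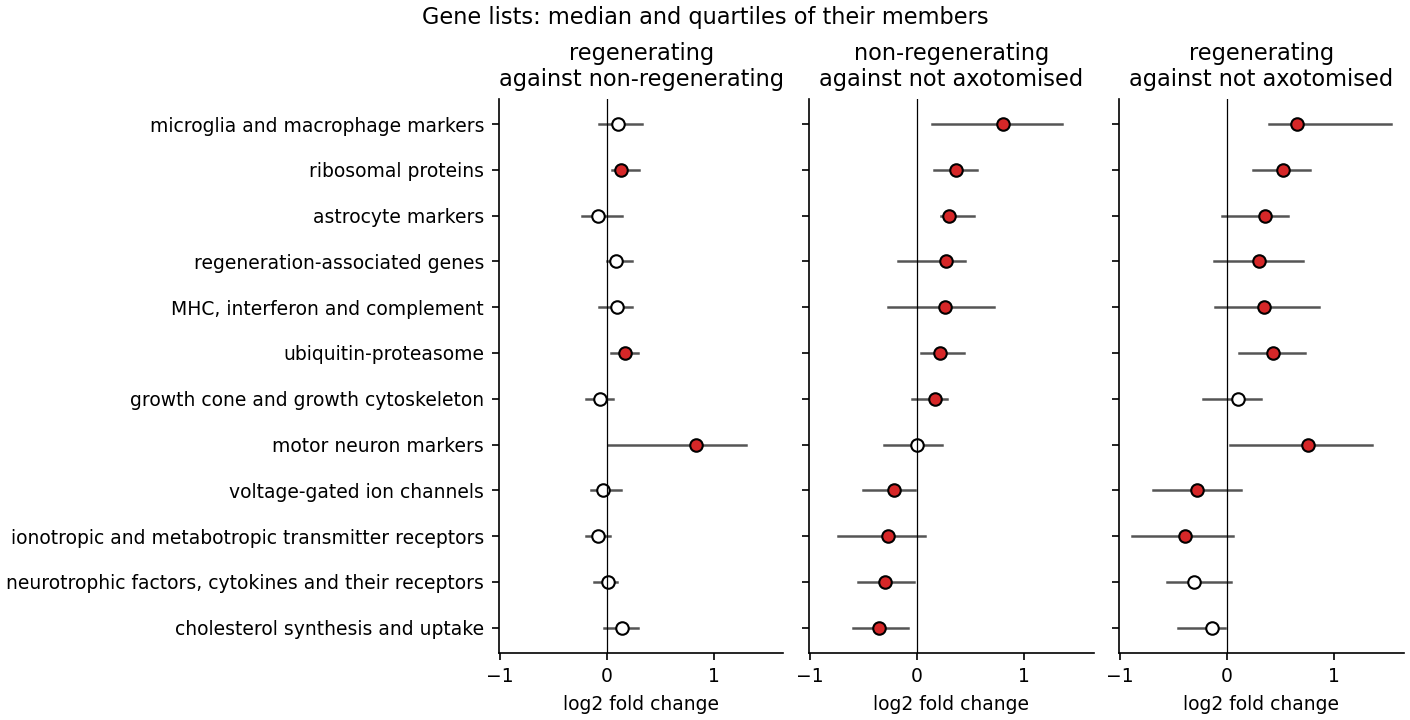
Median (circle) and quartiles (line) of log2 fold changes for the gene lists past the camera threshold in any comparison, with filled circles where the adjusted p with the preset correlation was under 0.05. Motor neuron markers have medians of 0.84, 0.00 and 0.76, and microglia and macrophage markers of 0.11, 0.81 and 0.65, in the order of the panels.

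The differences of regenerating and of non-regenerating neurons from not axotomised neurons were measured against the same 3 arrays, which makes them alike by itself. Of the 8 probe sets that rose in non-regenerating and the 29 that rose in regenerating neurons, 7 were shared, against 0.0125 for independent lists. As many top probe sets of simulated unchanged groups against the same controls shared 2.98 on average and up to 7. All 40 probe sets called in regenerating neurons differed in the same direction in non-regenerating neurons, as did all 40 top probe sets in each of 100 simulations, so neither count tells a shared change from shared controls. Within animals, 0 of the 40 differed between the axotomised groups in limma over all probe sets. Only 3 of 18625 probe sets passed in that comparison, so this count does not show that the 40 were alike in both groups. Across the 18625 probe sets, which are not independent replicates, the fold changes correlated with r = 0.93, where the simulated groups gave 0.86, and their covariance was 0.242 against a simulated 0.117. The simulated values hold the shared controls but no differences between whole arrays, so part of the excess may still come from these 3 arrays. The 3 not axotomised samples were not split between the comparisons.

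The relation of the changes with regeneration to the changes with axotomy was weak. Across the 18625 probe sets, log2 fold changes of regenerating against non-regenerating and of non-regenerating against not axotomised neurons correlated with r = 0.19 and a covariance of 0.0192. These comparisons share the non-regenerating arrays with opposite sign, and simulated unchanged groups gave r = -0.26 and a covariance of -0.0184. The simulated noise was independent between probe sets, while the real arrays differ as wholes, so the distance from simulated values is not a test of the relation. Over 35 splits of the animals that share no array, r had a median of 0.30 and ran from -0.06 to 0.48. The median was 0.39 over the 20 splits with MM17 in the regeneration comparison and 0.04 over the 15 with it in the axotomy comparison. The value moved with single animals. Without not axotomised MM15 r was -0.07, without MM17 it was 0.01, and without both it was -0.08, where unchanged groups of these sizes gave -0.22, -0.27 and -0.24. Without MM16, which did not stand apart, r was 0.08. Chat differed by 1.15 with regeneration and by 0.26 with axotomy, while Gfap differed by -0.03 and by 1.37.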

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

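The tests of explanations given here (neuronal material, single animals, shares of cells, name prefixes, RNA of neighbouring cells, 3 prime bias, scaling and yield) were chosen only after the results were seen, while the counts over other splits of the samples were planned.

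Of 142 groups of values, 13 had 1 sample far from the others, its gap to the nearest sample taking a large share of the whole range, where chance gives about 1 in 20, or 7.1. The array of non-regenerating MM17 held 7 of them. Among non-regenerating samples its share of signal in the 100 brightest probe sets was the highest (12.4% against 7.24% for the next, gap 0.605 of the range), and its median correlation with the other arrays the lowest (0.847 against 0.911, gap 0.668). It was the highest for Zdhhc19 (gap 0.578), Rab5b (0.584) and a probe set without a gene name that fell in regenerating neurons (0.62), and the lowest for 2 probe sets without a single gene name that rose there (0.65 and 0.652). Regenerating MM17 was the highest of its group for Zdhhc19 (0.735) and for the same fallen probe set (0.582). Non-regenerating MM16 was the lowest for Atf3 (log2 value 7.12 against 8.84, gap 0.659) and for Nefl (10.68 against 11.71, gap 0.671). Regenerating MM14 was the highest for Hspb1 (9.85 against 7.93, gap 0.656). Non-regenerating MM11 was the highest for the probe set without a gene name that rose in non-regenerating neurons (7.55 against 6.74, gap 0.716).

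Other splits of the same samples were fitted in the same way. For regenerating against non-regenerating neurons, 1 of 64 splits within animals, the real one, gave as many calls as 3, and the highest of the others was 1, from the split that swaps both MOON animals. This argues against chance for the count, at the smallest share that 64 splits can give, though no probe set passed in 10 of 21 other settings. For the motor neuron list, 1 of 64 splits gave a median as large as 0.84, and the highest other was 0.80. This list had the smallest camera p of its comparison and was the only one run, so its rank does not exclude chance. For non-regenerating against not axotomised neurons, chance cannot be excluded for the count, since 5 of 100 splits gave 8 calls or more. The highest other count was 1720, from the split that puts non-regenerating MM17 with not axotomised MM15 and MM19, which points to a structure of the samples that the groups do not hold. For the microglia and macrophage list 1 of 100 splits gave a median of 0.81 or more, with 0.54 as the highest other. This list, too, had the smallest camera p of its comparison and was the only one run, so its rank does not exclude chance. For regenerating against not axotomised neurons, 2 of 100 splits, with the real one, gave 40 calls or more, and 3 of 100 a microglia median as large as 0.65. The highest others were 50 and 0.68, above the real split, so few splits did as well but chance is not excluded for either. The split with 50 calls put both MOON animals with regenerating MM13, while 6 other splits that put both MOON animals together gave 0 calls each in limma. Among MM animals alone the real split gave 70 calls.

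The motor neuron markers were higher in regenerating neurons. More neuronal material in those samples is argued against by the general neuron markers outside the motor neuron list, whose median was -0.068 with an upper quartile of 0.08. A single animal or name prefix is argued against by the lowest list median without 1 animal or within 1 prefix, 0.595, without MM14. A larger share of motor neurons among the captured cells and a higher level of these genes per neuron cannot be told apart, since both raise most members, and 11 of 14 were higher. Of these, 8 rose adjusted over the list alone, while Nts, Ret and Ngfr were higher by only 0.04, 0.03 and 0.01. Of the 14 members, 11 are also in another of the lists, and a biological difference between the groups stays open as a hypothesis.

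Microglia and macrophage markers were higher in both axotomised groups than in not axotomised samples. A difference between name prefixes is argued against by the lower of the 2 list medians among MM animals alone, 0.684. A lower share of neurons in which other cell types gain as much as microglia is argued against by a score. This was the score of the list minus the mean score of oligodendrocyte, endothelial and fibroblast markers. It was higher after axotomy by 0.816 and 0.911 (exact permutation p = 0.0083 in both comparisons, two-sided, the smallest they can give). With astrocyte markers, which were higher themselves (medians 0.30 and 0.36), among the others, it was higher by 0.70 and 0.81 (same exact p). Against astrocyte markers alone it was higher by 0.352 and 0.503 (exact p = 0.0083 and 0.0167). The lists were chosen after their medians in these arrays were seen, so these exact p are not a separate test. The sizes restate that the other lists gained less than the microglia list. The score holds no neuron markers, so it cannot tell whether RNA of microglia took the place of neuronal RNA. General neuron markers had medians of -0.05 and -0.20, with 8 and 5 of 26 members higher, and did not pass camera. The captured samples did hold RNA of marker genes of other cells. Gfap and Mbp averaged 3116 and 3884 in regenerating and 3210 and 4357 in non-regenerating samples. The neurofilament gene Nefl averaged 3467 and 3621 there. Signals of different probe sets do not give shares of cells. RNA of microglia or macrophages beside the captured neurons may contribute, a hypothesis that laser capture does not rule out. The 13 brighter members of the microglia list were higher as a set, with a lower quartile of at least 0.476. C1qa averaged 1212 in non-regenerating against 440 in not axotomised samples. These values restate the rise of the list, and a response of the neurons would give them too, so they do not decide between the 2. Of the 26 members of the microglia list, 5 are also in another list, and a response of the neurons themselves to axotomy stays open and untested.

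The arrays of non-regenerating MM17 and not axotomised MM15 stood apart from the other 15. They came from different animals and groups but correlated with each other at r = 0.942, the highest value of each with any array. Non-regenerating MM17 correlated at r = 0.891 with the regenerating sample of its own animal. What the 2 arrays share was not settled by their labels. Stronger 3 prime bias is argued against by the ratios of these 2 arrays, at most 3.745 on the log2 scale, where the lowest of the others was 4.155. The scaling or spread of the signals is argued against by rank correlations, which no scaling moves, with medians of at most 0.790 for these 2 arrays and at least 0.874 for the others. A difference in amplification yield cannot be told apart from other properties of the arrays, since the title of 1 of the 2 names a high yield and the other names none. No biological explanation was tested.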

How the results depend on the processing

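The fits without the 2 arrays that stand apart, with the name prefix as a term and with MOON animals alone were chosen after seeing the data, and the other settings were planned. Named genes past the threshold kept their direction in each setting run, while genes that had not passed, such as Atf3 and Gap43 in the first comparison, turned in some. The motor neuron list kept its call in 22 of 23 settings (medians 0.60 to 0.98), and the microglia list in 25 of 25 (0.67 to 1.17) and 24 of 25 (0.51 to 1.04) for non-regenerating and regenerating against not axotomised neurons. The setting that ended both calls was the estimated correlation (adjusted p = 0.147 and 0.478). The numbers of calls moved most, and where no cause is given the cause was not tested. Signals near the background limit the dim probe sets, of which 12417 were left out.

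In the order regenerating against non-regenerating, non-regenerating against not axotomised and regenerating against not axotomised, 3, 8 and 40 probe sets passed. Quantile normalization gave 0, 17 and 215, and array weights 2440 and 3131 in the comparisons with not axotomised neurons. No offset gave 0 in the first, and an offset at the median gave 5 and 677 in the others. No filter gave 0 in the first, and a filter at the 70th percentile 20 in the third. With 1 fit over all samples the first 2 gave 1 and 23, and with 3 prime bias as a covariate the counts were 0, 16 and 4. With no replicate block, which gives up the pairing by animal, 0 passed in limma, with 217 at an unadjusted p under 0.05. MM animals alone gave 1, 3 and 70, with fewer samples. The fit without the 2 arrays gave 0 and 1 in the first and the third, and the name prefix as a term 202 in the third.

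Leaving out 1 animal in the first comparison gave 0 (without MM11, MM13, MM14 or MM17) to 3 calls, with 1 without MOON266. In the second, 1 array left out gave 2 (without not axotomised MM18) to 37 (without non-regenerating MM17), with 3 without MM15, MM11, MM13, MM14 or MOON266 and 5 without MOON265. In the third it gave 1 (without not axotomised MM15) to 1504 (without regenerating MM17), with 2 and 7 without MM18 and MM19 and 10, 19, 20 and 24 without MM13, MM11, MM14 and MOON266. The relation of the fold changes ran from -0.066 (without MM15) to 0.278 (without MM18), with 0.009 without MM17 and -0.084 without the 2 arrays.

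Centring each array on its median gave 350 calls in the third comparison and raised the medians of all probe sets, which moved all genes alike and turned lower lists above 0. In non-regenerating against not axotomised neurons these were receptors (0.092), voltage-gated channels (0.148), neurotrophic factors (0.066), cholesterol genes (0.004) and sensory ganglion markers (0.141), and in regenerating against not axotomised neurons voltage-gated channels (0.113). The filter at the 70th percentile, with fewer genes, gave 0.009 for receptors in the second comparison. The proteasome median of that comparison was 0.58 with centring, and with 1 array left out it ran from -0.081 (without MM15) to 0.361 (without MM18). In the 2 MOON animals alone, regenerating against non-regenerating medians turned for growth cone genes (0.106), proteasome (-0.034), ribosomal proteins (-0.10) and Schwann cell markers (0.253), and none of the 4 calls made there were among the 3.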

Other observations

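The groups described here were chosen only after their values were seen, and they are given as values. Several lists moved in single members in regenerating against not axotomised neurons while the list as a whole did not pass camera. Over all 18625 probe sets, 3274 were lower and 1113 higher there at an unadjusted p under 0.05 in limma. A fall adjusted over a list alone is therefore not set apart from that of other genes. Adjusted over the list alone, 9 cell cycle genes fell and 1 rose, with a median of -0.44 over 30 members, which was -0.05 with each array centred on its median and 0.07 with the filter at the 70th percentile. They included Nusap1 (-0.86), Top2a, a topoisomerase of dividing cells (-1.17), Ccne1 (-0.93) and Kif11 (-0.93), at signals near 40 to 60 in regenerating neurons. Of 37 synaptic vesicle genes 5 fell adjusted over the list alone, such as Syn1, which encodes synapsin 1 (-2.07, from 867 to 219), Amph (-1.25), Syt1 (-0.96) and Sv2c (-0.88), with a list median of -0.12. At an unadjusted p under 0.05 in limma, 9 of the 37 were lower and 1 was higher. Of the sensory ganglion markers, P2rx3, an ATP receptor of nociceptors (-1.49), and Scn10a, a sodium channel of nociceptors (-1.12), were among 4 that fell adjusted over the list alone, and Calca among 2 that rose. Of the transmitter synthesis and uptake list 5 rose and 4 fell adjusted over the list alone, among them Slc18a2, the vesicular monoamine transporter (-1.46, from 155 to 49.0). Fabp7, of the Schwann cell list (1.09), and Pltp, of the ependymal list (1.13), rose adjusted over those lists alone, where 2 rose and 2 fell, and 2 rose and 3 fell, with medians of -0.12 and -0.47.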
